A study of Homo sapiens with 4 samples.

How the data were processed

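The series holds 4 libraries from SH-SY5Y cells: a WT input, a WT H4K5la immunoprecipitation, a DNAJC12KO input and a DNAJC12KO H4K5la immunoprecipitation, 1 of each. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 minutes, sonicated for 8 minutes and incubated with 2 μg of antibody, and DNA was fragmented to 300 bp for the library. The protocols also name a control IgG and spike-in chromatin, which were not used here. Per the submitters' processing notes, MACS2 2.2.6 and the build hg38 were used. The aligner, the read filters, the peak-calling options and any scaling by spike-in are not given in the sources used here. Nor is it given whether the input library was the control in peak calling, so the background behind each fold may come from the input or from the immunoprecipitated library itself.

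The deposited files are 1 peak list in broad peak format per genotype. Each was taken as the list of that genotype's immunoprecipitated library because the sample descriptions name it for the genotype's input and immunoprecipitated library alike. Peaks were thus called by the authors per library, not on pooled samples. The authors' values per peak are a score, a fold enrichment (a linear ratio over the background), and the -log10 p and -log10 q of the peak caller. In a broad peak list these are averages over the peak. The score was not used. Both lists stop at a -log10 q of about 1 (lowest value 1.03 in the WT list and 1.01 in the DNAJC12KO list). A place without a peak is thus a place below the authors' threshold, or one that was not searched for peaks. The lists carry no counts, and signal tracks were not used here, so the depth of each library is unknown. A difference in depth between the libraries would change the number of peaks called and their fold. The columns of other samples numbered 0.

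Genes came from a RefSeq table of GRCh38.p14, of which 58957 records on chromosomes 1 to 22, X and Y were used, 19862 of them protein-coding; 831 records on other sequences were left out. The table gives the start and end of each gene but no strand and no exons, and no genome sequence was used. The planned window of 3 kb around the transcription start site was therefore replaced by windows of 3 kb around either end of the gene record. The planned classes promoter, exon, intron and intergenic were replaced by gene end, inside a protein-coding gene, inside another annotated gene, and outside annotated genes, in that order. These changes were made after seeing the data. Length without assembly gaps was replaced by the annotated span of each chromosome without gene-free stretches of more than 1 Mb. Coordinates are 1-based.

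Overlaps were counted with bedtools 2.31.1 at a minimum of 1 bp. All else was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9. Overlap and position were set against 100 random placements with the same widths on the same chromosome and, added after seeing the data, against 100 sets in which each peak was moved by 50 to 500 kb. Shares have exact binomial (Clopper-Pearson) 95% intervals. A protein-coding gene counted as carrying a peak when a peak overlapped the window at either end by at least 1 bp. For 18 gene lists, 15 written by hand and 3 gene families, the number of members with a peak was placed among 10000 random lists of the same size matched on gene length in 10 bins, with ties counted as midway. The percentile describes these libraries and is no test between genotypes. The lists, the named genes, the settings of the tests and the alternatives not said below to be added were chosen before the data were examined.

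Named genes followed this rule. They are DNAJC12 and COL1A1; the 8 genes with the highest -log10 q of a peak at an end in each of the WT-only and DNAJC12KO-only sets; and the 8 shared genes with the best value of the worse of both ranks; ties were broken by fold and then by symbol. Of every gene list, up to 4 members with such a peak are named by best rank. Last come the 5 peaks with the highest -log10 q of each list with their nearest gene. Genes named for the crowded stretches of chromosomes, the members with a peak inside the gene only, and H2AJ were chosen after their values were seen.

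The local background of each peak was inferred from the authors' fold and -log10 p. A pileup k over a background b satisfies (k + 1)/(b + 1) = fold, and its Poisson upper tail gives p; the larger solution was taken. These are approximate, model-based values in fragments after the authors' scaling. In a test on simulated data, 1000 backgrounds were recovered with a largest error of 0.00193%. The simulated values were made with the same formula, so that test checks the calculation only. The authors' values are averages over a broad peak, for which the formula need not hold, and the error from this was not simulated. In the simulated overlap, 150 of 150 planted shared peaks were found in a list of 1937. Of 200 random lists of 25 genes drawn from the 19862, 6 lay above the middle 95% in the WT gene set, and of 200 lists with 4 planted members, 200 did. The planted peaks and members were nearly sure to be found, so those results check the counting only. Lists with fewer planted members were not simulated.

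Alternatives were a -log10 q of at least 2 or 5, a fold of at least 4, lists cut to equal length by -log10 q, all sequences, merging peaks within 1 kb, other definitions of overlap, windows of 1 or 10 kb, absence within 10 kb, and peaks anywhere in the gene. Added after seeing the data were the moved placements, random lists matched on gene density within 500 kb, leaving out the H4C16 peak with every peak of inferred background above 3, and leaving out chromosomes 7 and 17.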

Results

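Lactylation of lysine 5 of histone H4 (H4K5la), a modification that uses lactate as its source, was profiled by chromatin immunoprecipitation sequencing in SH-SY5Y cells, a human neuroblastoma line. Wild-type (WT) cells were compared with cells in which DNAJC12 had been knocked out (DNAJC12KO). DNAJC12 encodes a co-chaperone of the aromatic amino acid hydroxylases. Each genotype had 1 immunoprecipitated library and 1 input library, 4 libraries in all, and the data consisted of 1 peak list per genotype. The lists give no read counts, so the depth of each library is unknown. With 1 library per group, every difference between the genotypes reported here has no replicate check, and no test between genotypes was made. Fold enrichment and -log10 q are the authors' own values for each peak. They serve to describe and rank peaks within a list, and to cut both lists at the same value. Intervals are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only.

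The first question was where H4K5la peaks lay at the knocked-out gene and at COL1A1, the fibrillar collagen gene that the study is known to have followed up. Neither list had a peak at DNAJC12 (chromosome 10, 67796669 to 67838188). The nearest peak lay 2730 kb from the gene in the WT list and 2126 kb in the DNAJC12KO list. COL1A1 (chromosome 17, 50184101 to 50201631) held 1 peak in each list, at different places inside the gene. The WT peak spanned 50186065 to 50186876 (fold 3.94, -log10 q 1.81), and the DNAJC12KO peak spanned 50191971 to 50192382 (fold 3.22, -log10 q 1.10). Only the WT peak came within 3 kb of an end of the gene record, at a distance of 1964 bp. COL1A1 is transcribed towards lower coordinates, so that end is the one away from its promoter. With a window of 10 kb around the gene ends, both lists counted COL1A1, and with a window of 1 kb neither did. The absence of peaks at DNAJC12 gives no information on whether the gene was deleted, because the WT list has none there either.

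The strongest peak of the DNAJC12KO list covered H4C16, a gene for histone H4, where the WT list had no peak. It spanned 14770606 to 14771288 on chromosome 12 and enclosed the whole gene record (14770720 to 14771131), with 114 bp beyond its start and 157 bp beyond its end. Its fold was 35.0 and its -log10 q 154, while the next highest fold of that list was 5.14 and the next highest -log10 q 5.91. The same peak touched the end of the neighbouring record LOC105369669, which is counted with H4C16 below for that reason. No WT peak and no other DNAJC12KO peak lay within 100 kb of it. The neighbouring histone gene H2AJ, 3.12 kb away, had no peak. Of the other 14 histone H4 genes, 0 had a peak within 3 kb of an end in either list.

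**Figure D1:**
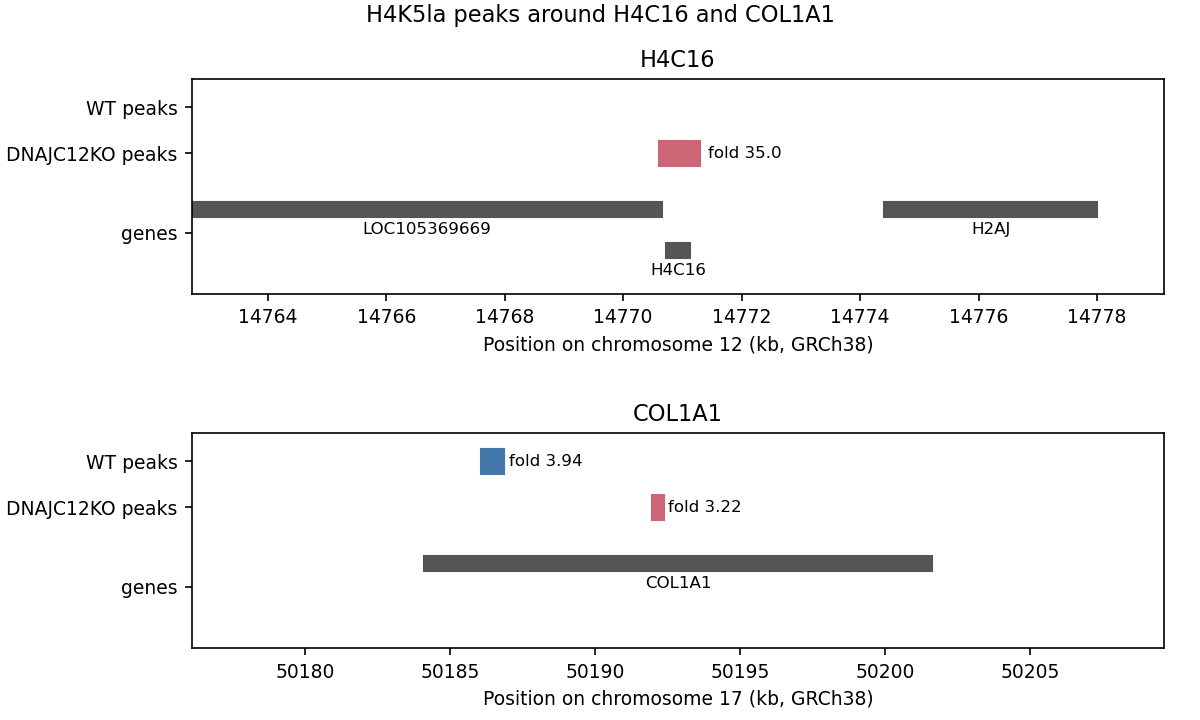
Peaks of the WT and DNAJC12KO lists (coloured boxes, with the authors' fold) and protein-coding gene records (grey boxes) around H4C16 and COL1A1, against position in kb on GRCh38. The DNAJC12KO peak of fold 35.0 encloses H4C16, and the COL1A1 peaks of the WT list (fold 3.94) and the DNAJC12KO list (fold 3.22) lie at different places.

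The remaining top-ranked peaks lay mostly outside protein-coding genes, several at places shared by both lists. The WT list was led by a peak on chromosome 1 at 144103150 to 144104740 (fold 3.66, -log10 q 5.23), 16.8 kb from the immunoglobulin pseudogene IGKV1OR1-1. The DNAJC12KO list had its own peak there, at 144103125 to 144104814 (fold 3.99). A peak on chromosome 5 at 49599549 to 49600847 (fold 2.82), 795 kb from EMB, was second in the WT list. It overlapped the DNAJC12KO peak at 49600544 to 49600887 (fold 2.77). On chromosome 21, a peak at 8234306 to 8234646 (fold 1.91, -log10 q 5.91), 4.59 kb from CDC27P9, appeared in the DNAJC12KO list alone. The WT list also ranked high a peak inside PLEKHM2 on chromosome 1 (15716566 to 15716867, fold 5.66) and a peak on chromosome 7 (1283975 to 1284278, fold 5.32), 46.6 kb from UNCX. The shared places and the chromosome 21 peak had a high inferred background: 8.41 (WT) and 6.20 (DNAJC12KO) fragments on chromosome 1, 15.3 in each list on chromosome 5 and 69.5 on chromosome 21, against medians of 1.64 and 1.75 over the lists. Each list had a further top-ranked peak on an unplaced sequence.

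The second question was how the 2 lists compare in size and position. On chromosomes 1 to 22, X and Y, the WT list held 1937 peaks covering 997 kb and the DNAJC12KO list 2743 peaks covering 1422 kb. The ratio of peak numbers was 1.42. Among peaks with a fold of at least 4 the order was the opposite, with 548 WT peaks and 475 DNAJC12KO peaks. That cut was not alike in the lists, because the median inferred background was higher in the DNAJC12KO list and the same fold then needs a higher pileup. Peaks were short and weak in both lists. The median width was 453 bp in the WT list and 460 bp in the DNAJC12KO list, the median fold was 3.82 and 3.69, and the median -log10 q was 1.47 and 1.48. A -log10 q of at least 2 was reached by 10.4% of WT peaks and 9.99% of DNAJC12KO peaks.

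Few peaks were shared. Of the 1937 WT peaks, 172 (8.88%, interval 7.65 to 10.2%) overlapped a DNAJC12KO peak by at least 1 bp, and of the 2743 DNAJC12KO peaks, 173 (6.31%, interval 5.43 to 7.28%) overlapped a WT peak. Placing the WT peaks at random on their chromosomes gave a mean of 4.06 overlapping peaks and at most 9 in 100 placements. Moving each WT peak by 50 to 500 kb gave a mean of 26.2 and at most 37. Such moves keep the stretch of chromosome but not the position inside or near genes. Within 10 kb, 778 WT peaks (40.2%) had a DNAJC12KO peak, against a mean of 342 after such moves.

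Peaks of both lists lay mainly inside or near protein-coding genes. In the WT list, 25.1% of peak centres (interval 23.2 to 27.1%) lay within 3 kb of an end of a protein-coding gene record, 60.9% elsewhere inside such a gene, 3.51% inside another annotated gene and 10.5% outside annotated genes. The DNAJC12KO shares were 21.9% (interval 20.4 to 23.5%), 58.7%, 4.52% and 14.9%. Random placement on the same chromosomes put 9.22% of centres at gene ends for each list. Moves of 50 to 500 kb put 17.03% there for the WT list and 16.2% for the DNAJC12KO list. The median peak had 16 protein-coding genes within 500 kb in each list, against a mean of 6.73 (WT) and 6.81 (DNAJC12KO) for the medians of random placements. After moves of 50 to 500 kb the means were 16.04 (WT) and 15.02 (DNAJC12KO), close to those of the peaks.

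**Figure D2:**
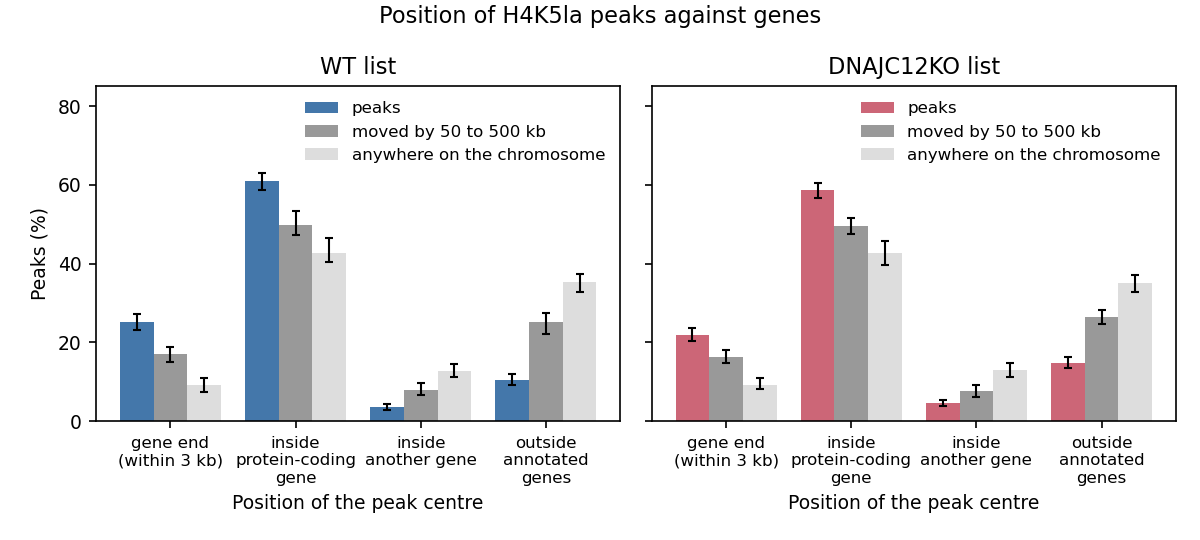
Share of peak centres (%) in each position class for the WT list and the DNAJC12KO list, beside the mean of 100 sets of peaks moved by 50 to 500 kb and of 100 sets placed anywhere on the same chromosome. Lines on the peak bars are exact binomial 95% intervals and lines on the other bars the range over the 100 sets; gene ends hold 25.1% of WT and 21.9% of DNAJC12KO peaks.

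Peaks were crowded on chromosomes 7 and 17 in both genotypes. Chromosome 7 carried 335 WT peaks (17.3%, interval 15.6 to 19.1%) and 422 DNAJC12KO peaks (15.4%, interval 14.1 to 16.8%), with 4.71% of the protein-coding genes. Chromosome 17 carried 288 WT peaks (14.9%, interval 13.3 to 16.5%) and 395 DNAJC12KO peaks (14.4%, interval 13.1 to 15.8%), with 5.83% of the genes. The first 3 Mb of chromosome 7, around GPER1, MICALL2, INTS1 and ADAP1, held 119 of its WT and 122 of its DNAJC12KO peaks. The stretch from 81 to 83 Mb of chromosome 17, around CEP131, GCGR, FASN and SLC16A3, held 92 WT and 102 DNAJC12KO peaks. Peaks per Mb of annotated span ranked chromosome 17 first (3.65 WT, 5.01 DNAJC12KO), followed by chromosome 19 (2.31 and 3.22) and chromosome 7 (2.17 and 2.74). Among the 20 chromosomes with at least 20 WT peaks, the DNAJC12KO share divided by the WT share ranged from 0.788 on chromosome 10 to 1.79 on chromosome 12.

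**Figure D3:**
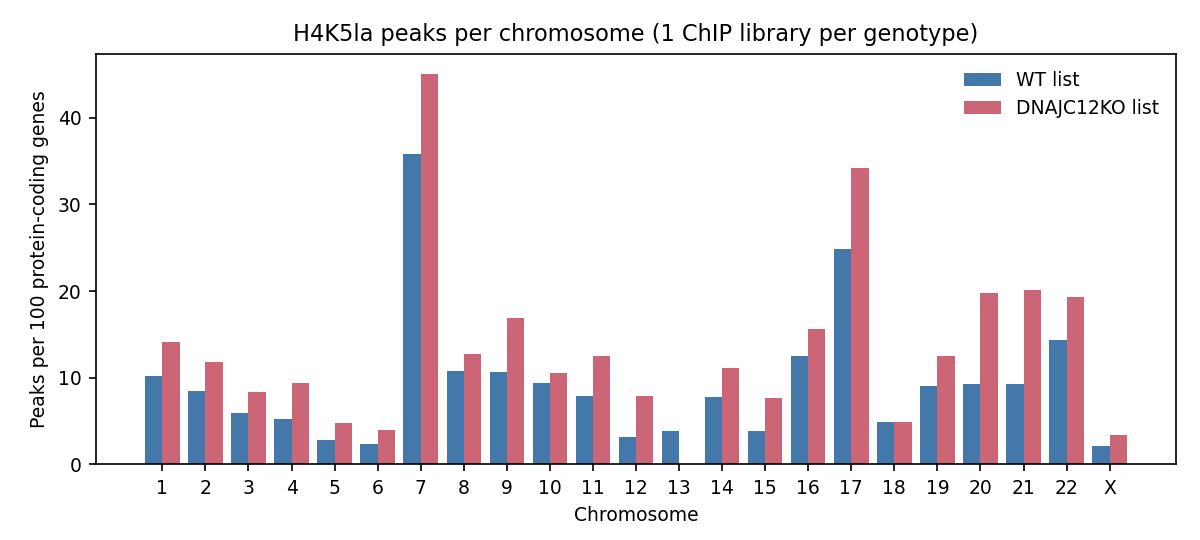
Peaks per 100 protein-coding genes on each chromosome in the WT list and the DNAJC12KO list; each bar is 1 peak list, with no error bar because each genotype had 1 ChIP library. Chromosome 7 stands at 35.8 (WT) and 45.1 (DNAJC12KO) and chromosome 17 at 24.9 and 34.1.

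The third question was which genes carried a peak at an end. Of 19862 protein-coding genes, 636 did so in the WT list and 766 in the DNAJC12KO list. Both lists shared 160 of these genes, against 24.5 for independent sets of the same sizes. That number takes every gene as equally likely to carry a peak, although peaks lay in gene-dense stretches and neighbouring genes can share a peak. No number from moved peaks is given for genes. A gene also counted as shared when the lists had a peak at different ends. In the WT list alone were 476 genes, and in the DNAJC12KO list alone 606. The order was the opposite with lists cut to equal length (506 WT-only and 437 DNAJC12KO-only genes) and with a fold of at least 4 (190 and 142). Among the shared genes, the best-ranked was EEF1A2, a translation elongation factor of neurons and muscle, with a fold of 4.78 in the WT list and 4.77 in the DNAJC12KO list. It was followed by ACTA1, skeletal muscle actin (4.02 and 4.11), CEP131, a centrosomal protein gene (4.02 and 4.23), and FGF22 (4.57 and 4.27). The next were MYO1G (4.02 and 3.84), the Integrator subunit gene INTS1 (3.92 and 4.35), PTDSS2 (4.24 and 4.24) and POR (3.75 and 4.14), whose peaks also lie at an end of its neighbour TMEM120A. Only at ACTA1 and CEP131 did these best-ranked WT and DNAJC12KO peaks overlap. At the other genes of this set the best-ranked peaks lay at different places. At PTDSS2, however, another WT peak at 489194 to 489961 lay inside the DNAJC12KO peak at 488798 to 490068. At INTS1, another WT peak at 1469666 to 1471047 enclosed a DNAJC12KO peak at 1469959 to 1470369. INTS1 carried 12 WT and 11 DNAJC12KO peaks in its record, and CEP131 carried 3 and 9.

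The genes with the highest -log10 q found in the WT list alone included SCRT1, a neuronal transcriptional repressor (fold 5.14), PDGFA, a growth factor gene (4.67), and MEFV, the pyrin gene (5.01). GDPD5 and KLHL35 shared a peak (fold 5.14), as did ATP6V1F and SPMIP1 (4.71), and LOC124904417 completed the set (5.19). In the DNAJC12KO list alone, after H4C16 and LOC105369669, they were REXO1 (fold 5.06), PRSS51 (5.01), the membrane metalloproteinase gene MMP15 (5.12) and the Mediator subunit gene MED26 (4.94), then RNF208 (4.71) and C19orf33 (4.77). Absence at the ends did not always mean absence nearby. The nearest DNAJC12KO peak was 4.05 kb from PDGFA, the nearest WT peak was 3.74 kb from RNF208, and REXO1 held a WT peak within its record at 1828563 to 1829002.

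Of the 18 gene lists, collagens and extracellular matrix stood apart in the WT list, with 4 of 26 genes against a mean of 0.663 in random lists (percentile 99.8). They were LOXL2, a lysyl oxidase gene (fold 3.78), COL6A1 (3.82), P4HB, a prolyl hydroxylase subunit gene (3.18), and COL1A1. That the study followed up COL1A1 was known when the lists were written, so the percentile is not independent of the study's own choice. The DNAJC12KO list had 0 of 26 at the ends (percentile 22.2), but COL18A1, COL1A1, COL5A1 and COL6A2 had a DNAJC12KO peak inside the gene or at its ends. On that wider count the list had 7 WT and 4 DNAJC12KO members, at percentiles 99.9 and 84.5, and whether the genotypes differ was not tested. The WT count at the ends was 1 with a window of 1 kb, 2 without chromosomes 7 and 17, and 0 among peaks with a -log10 q of at least 2 or a fold of at least 4. Of the 36 percentiles over the 18 lists, 4 lay outside the middle 95%, the other 3 being low values of the olfactory receptor genes in both lists and of the ZNF genes in the WT list. With random lists matched on gene density, 6 did.

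Glycolysis and lactate genes were represented by PFKL, a phosphofructokinase gene, and SLC16A3, a lactate exporter gene, in both lists. That is 2 of 25 genes, at percentile 86.8 in the WT list and 83.1 in the DNAJC12KO list. The PFKL peaks had a fold of 4.28 (WT) and 3.77 (DNAJC12KO), and the SLC16A3 peaks 3.67 and 3.96. These best-ranked peaks of the 2 lists overlapped in neither gene. With a window of 1 kb, a -log10 q of at least 2 or a fold of at least 4, the DNAJC12KO list had 0 members, and the WT list 2, 1 and 1. Without chromosomes 7 and 17, each list had 1. Counted inside the gene or at its ends, each list had 4, with GPI and PFKP added in the WT list (percentile 94.5) and PFKFB3 and PFKP in the DNAJC12KO list (percentile 88.98).

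Several lists had 1 member at the gene ends in the DNAJC12KO list and 0 in the WT list. TH, tyrosine hydroxylase, stood for the 20 catecholamine, serotonin and tetrahydrobiopterin genes (fold 3.63, percentile 67.3). ATF3 stood for the 15 genes of the unfolded protein response (3.11, percentile 69.8), EPAS1 for the 15 hypoxia genes (3.52, percentile 72.5) and E2F1 for the 28 cell cycle genes (3.93, percentile 44.1). The corresponding WT percentiles were 28.0, 29.0, 30.4 and 15.8. None of these 4 genes kept its peak with a -log10 q of at least 2 or a fold of at least 4, TH and ATF3 lost theirs with lists cut to equal length, and only TH kept it with a window of 1 kb. The 0 in the WT list did not hold for the catecholamine list with a window of 10 kb (1 WT and 3 DNAJC12KO members) or with peaks inside the gene counted as well (DBH in the WT list, TH and SLC6A3 in the DNAJC12KO list). It did not hold for the cell cycle list with a window of 10 kb (1 member each). Genes of other tissues had 2 of 30 members in the WT list, ACTA1 and the surfactant gene SFTPC (fold 4.18), and 1 in the DNAJC12KO list, ACTA1 (percentiles 79.0 and 44.4).

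No member had a peak at an end in either list among 31 ribosomal protein genes (percentiles 11.9 WT and 9.01 DNAJC12KO), 24 housekeeping genes (20.3 and 17.1) and 23 oxidative phosphorylation genes (18.3 and 15.3). The same held for 15 writers and erasers of histone lactylation (29.9 and 26.4), 22 heat shock proteins and co-chaperones (23.4 and 19.8) and 24 neuronal and axonal genes (28.1 and 24.3). It also held for 20 adrenergic (24.7 and 21.2) and 20 mesenchymal neuroblastoma identity genes (26.6 and 22.9). For each of these lists on its own, a count of 0 was within what random lists gave, which in lists of this size could hardly be otherwise. With a window of 10 kb, only the oxidative phosphorylation genes kept 0 members in both the WT and the DNAJC12KO list. With peaks inside the gene counted as well, the ribosomal protein, housekeeping and oxidative phosphorylation genes kept 0 in both, and the others did not. The 389 olfactory receptor genes had 0 in both lists (random means 15.2 and 17.9, percentile 0 in each). ZNF genes had 5 of 518 in the WT list (random mean 18.6, percentile 0.01) and 20 in the DNAJC12KO list (random mean 21.5, percentile 37.5). The WT and DNAJC12KO counts of ZNF genes were 1 and 1 with a -log10 q of at least 2, and 1 and 5 with a fold of at least 4. ZNF genes numbered 5 and 15 with lists of equal length, 2 and 9 with a window of 1 kb, and 15 and 28 with 10 kb. Counted inside the gene or at its ends, they were below the random lists in both, with 12 WT (random mean 36.4, percentile 0) and 27 DNAJC12KO members (random mean 46.3, percentile 0.075). The best-ranked were ZNF282, in both lists (fold 5.14 and 4.10), and ZNF316, ZNF775 and ZNF213, with a peak at an end in the DNAJC12KO list alone (4.07, 3.82 and 4.03). ZNF316 also held 3 WT peaks inside its record. Replication-dependent histone genes had 0 of 69 in the WT list and H4C16 alone in the DNAJC12KO list (percentiles 4.93 and 17.1). Random lists drew each gene on its own. For gene families whose members lie side by side, they vary too little, so the low percentiles can be too extreme.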

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

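The lists also hold peaks on unplaced sequences, which the comparisons above leave out; they are listed because a signal appeared in data outside the main measurement. The WT list had 6 such peaks on 4 sequences and the DNAJC12KO list 12 on 5 sequences. Of these, 4 WT peaks and 3 DNAJC12KO peaks overlapped a peak of the other list. KI270736.1 carried 5 DNAJC12KO peaks and no WT peak. The median inferred background of these peaks was 4.06 fragments in the WT list and 5.11 in the DNAJC12KO list, against 1.64 and 1.75 over the primary chromosomes.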

How the results depend on the processing

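No paired analysis was possible because each group had 1 library and no result comes from a test across samples. The alternatives that need repeats, assembly gaps or all transcription start sites were not run. Depth is unknown, and peaks near the authors' threshold make up most of both lists, so counts fall steeply with any stricter threshold. The moved placements, the gene density matching and the runs without chosen peaks or chromosomes were added after seeing the data. Merging peaks within 1 kb, adding all sequences, leaving out the H4C16 peak with the peaks of high background, and asking for absence within 10 kb kept each main count or share within its interval or within 1.5 times.

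With a -log10 q of at least 2, there were 202 WT peaks (95.8 kb) and 274 DNAJC12KO peaks (138 kb); 3.47% and 2.55% overlapped, 27.2% and 24.5% lay at gene ends, 39.4% of DNAJC12KO peaks lay on chromosomes 7 and 17, and genes numbered 1 in both lists, 82 in the WT list only and 90 in the DNAJC12KO list only. With a -log10 q of at least 5, only 1 WT peak (1.59 kb) and 3 DNAJC12KO peaks (2.71 kb) remained, with ratios of 3 in number and 1.71 in length, 100% and 33.3% overlapped, 0% and 33.3% at gene ends, 0% on chromosomes 7 and 17, and 0, 0 and 2 genes; shares of so few peaks say nothing about the lists. With a fold of at least 4, 548 WT peaks (265 kb) and 475 DNAJC12KO peaks (229 kb) reversed the ratios to 0.867 in number and 0.863 in length; 2.01% and 2.32% overlapped, 25.7% of DNAJC12KO peaks lay at gene ends, 23.0% and 23.4% lay on chromosomes 7 and 17, and genes numbered 23, 190 and 142. The cause of the reversal was not tested. With a -log10 q of at least 2 or a fold of at least 4, both lists were cut, so each peak had fewer peaks of the other list to overlap. The lower shares overlapped under these settings do not show that stronger peaks are shared less. Lists of equal length had ratios of 1, by construction, and 1.02 in length, with 6.76% of WT peaks overlapped, and reversed the order of the WT-only and DNAJC12KO-only genes (506 and 437).

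Without chromosomes 7 and 17, WT peaks covered 643 kb, 5.86% of WT and 4.05% of DNAJC12KO peaks overlapped, and 100 genes were in both lists. The shares overlapped were 4.65% and 3.46% when 50% of the peak had to be covered, 3.46% and 2.44% when the overlap had to be reciprocal, and 40.2% and 29.7% within 10 kb. A window of 1 kb put 9.50% of WT and 8.31% of DNAJC12KO peaks at gene ends and gave 34 shared, 230 WT-only and 310 DNAJC12KO-only genes. A window of 10 kb gave 55.8%, 50.1%, 587, 809 and 1145. Against moved placements, the observed overlap was 6.55 times (WT) and 6.42 times (DNAJC12KO) the mean, not 42.4 and 38.3 times, and the share at gene ends 1.48 and 1.36 times, not 2.73 and 2.38 times. Of 1036 values of single genes and gene lists under the alternatives, 216 moved; with a -log10 q of at least 2 or 5 and a fold of at least 4, the 34, 59 and 24 that moved were lower, and with a window of 10 kb the 23 that moved were higher. Matching random lists on gene density moved 2 of 36 percentiles, those of the histone genes, to 0.325 (WT) and 1.89 (DNAJC12KO). These lists too drew each gene on its own and did not keep neighbouring genes together, so such percentiles can be too extreme.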

Other observations

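Some gene-dense stretches outside chromosomes 7 and 17 also drew peaks in both genotypes. The window from 2 to 3 Mb of chromosome 1, with PLCH2 and PANK4 among the genes in both lists, held 22 WT and 29 DNAJC12KO peaks. The window from 143 to 144 Mb of chromosome 8, with RHPN1, ZC3H3, GFUS and MAPK15, held 25 and 20. Over 3033 windows of 1 Mb, the numbers of WT and DNAJC12KO peaks had a Spearman correlation of 0.639 across windows, which are not independent replicates. Most windows had no peak: 548 had a WT peak, 722 a DNAJC12KO peak and 415 both. The correlation with the number of protein-coding genes was 0.441 for WT and 0.489 for DNAJC12KO peaks, and no value expected from gene number alone was computed.

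Chromosome 13 had 13 WT peaks, from 19.0 to 114 Mb, and 0 DNAJC12KO peaks, where the WT share would give 18.4. The peak numbers in the DNAJC12KO list run without a gap (0 numbers missing). Whether this chromosome was searched for peaks in that library is not given in the sources used here, so the 0 is not shown to be an absence of peaks. Its 336 protein-coding genes stayed in the gene counts and gene lists. Any list member among them may thus have had no chance of a DNAJC12KO peak.

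In the patterns that follow, the tests of gene density, of gain at the H4C16 locus, of H4C16 sequence from outside the genome and of unrelated lists were chosen after the result was seen. The crowding of peaks on chromosomes 7 and 17 was in both lists, and gene density alone is argued against, because both chromosomes hold 10.5% of protein-coding genes and 32.2% of WT (interval 30.1 to 34.3%) and 29.8% of DNAJC12KO peaks (interval 28.1 to 31.5%). A candidate explanation is extra DNA copies, since gains of chromosome 7, 2p and 17q are known in this line: in both lists peaks per gene were at least 3.05 times as frequent on 17q as on 17p and at least 2.07 times on 2p as on 2q, although 2q was low (4.47 WT and 8.43 DNAJC12KO peaks per 100 genes) and chromosome 2 as a whole held 5.47% and 5.40% of peaks with 6.31% of genes. The inferred background was also higher on 17q than on 17p (2.01 against 1.48 fragments WT, 2.19 against 1.61 DNAJC12KO) and on 2p than on 2q (1.99 against 1.53, 2.17 against 1.62), but on 1q, where it was also higher than on 1p (2.09 against 1.48, 2.29 against 1.63), peaks per gene were only 1.24 and 1.21 times those on 1p. A gain of all of chromosome 7 does not account for the difference between its arms, with 59.0 peaks per 100 genes on 7p and 24.8 on 7q (WT) and 69.0 and 33.8 (DNAJC12KO), at backgrounds of 1.92 and 1.93, and 2.18 and 2.13. Most peaks of 7p lay in its first 3 Mb, with 119 of 177 in the WT list and 122 of 207 in the DNAJC12KO list. The difference between the arms rests largely on that stretch and does not argue against a gain for the rest of the chromosome. Copy number was not measured and base composition was not tested. Arms were compared on chromosomes 1, 2, 7 and 17 only, and whether this line has gains of other arms than those named was not examined. Whether the background comes from the input is not given in the sources used here.

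The H4C16 peak of the DNAJC12KO list had an inferred pileup of 126 fragments over a background of 2.63, where the median peak had 9.43 over 1.75. A gain of a far longer stretch as the only source is argued against by the 683 bp width of the peak. The 0 other DNAJC12KO peaks within 100 kb cannot decide on a gain. Chromosome 12 had 0.624 DNAJC12KO peaks per Mb, so a count of 0 was likely there in any case. The mark at histone H4 genes in general is argued against by 0 of the other 14 H4 genes with a peak. H4C16 sequence from outside the genome, such as a construct or amplified DNA in that library, stays open: the peak passes the ends of the record by at most 157 bp, but a peak of median width centred on so short a gene would do the same, so it cannot be told apart from a true peak. A change of H4K5la at this gene in DNAJC12KO cells stays open as well and was not tested.

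Few peaks were shared by the lists. Unrelated lists are argued against, because 172 WT peaks overlapped where moved placements gave at most 37. Those placements keep the stretch of chromosome but not the position inside or near genes, so they do not control for it. Calls close to the threshold may account for the low sharing, but the test did not decide: among the 25% of DNAJC12KO peaks with the highest -log10 p, 7.29% overlapped (interval 5.46 to 9.50%), against 4.81% (interval 3.33 to 6.69%) of the lowest. The WT shares were 11.0% (interval 8.31 to 14.1%) and 7.22% (interval 5.08 to 9.89%). A difference between the genotypes stays open and cannot be told apart from chance calls with 1 library each.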
